A study of Homo sapiens with 6 samples.

How the data were processed

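Whole blood was drawn into RNA-stabilizing PAXgene tubes, and libraries were made from total RNA with a stranded Illumina TruSeq Total RNA kit, per the labels' protocols. The 6 libraries fall into 2 groups of 3: patients sampled after a first clinical event who later received a diagnosis of relapsing remitting multiple sclerosis (MS-C), and healthy controls (HC). Each library was taken to come from a separate person, which the labels do not state outright.

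For each library the authors deposited 1 table of 58219 Ensembl gene IDs with RSEM's expected counts and TPM values. Expected counts, per the file headers, are estimated counts that RSEM, a tool that shares reads with several possible origins among genes, assigned to each gene. TPM, a measure of relative transcript abundance, was deposited beside them, per the file headers, and is scaled for gene length and to a fixed total. TopHat2 and RSEM are named without versions, and the build hg19, per the submitters' processing notes; the order of the steps, the use of strand and the annotation are not given in the sources used here. Gene symbols, types and coordinates were taken from GENCODE 29. Of the IDs, 57881 were found there without regard to version, 55008 (94.5%) with the same version, and 338 not at all; the last held at most 0.579% of a library's counts. GENCODE 29 is on build GRCh38, so the printed coordinates are those of GRCh38 and not of the build in the notes.

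Expected counts were rounded to whole numbers. Genes on the Y chromosome, genes of X inactivation and X genes with a Y copy (605 in all) were left out of every test and of the library sizes. The main test was edgeR's (4.0.16) quasi-likelihood F test in R 4.3.3, with TMM normalization, filterByExpr (minimum count 10) and Benjamini-Hochberg adjustment, on the coefficient MS-C minus HC, at adjusted p below 0.05; standard errors are those of the fitted log2 fold change. TMM factors ran from 0.743 to 1.13. CPM values are TMM-scaled unless a share of all counts is named. The 29 gene lists fixed before the data were examined were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, adjusted over the 29 lists, and with fry; camera was also run with the correlation estimated per list. Group means of list levels and of shares of counts were compared with two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3. Fold changes are MS-C relative to HC.

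Named genes followed a rule fixed before the data were examined: up to 12 genes per direction past the test with a mean of at least 1 CPM, a symbol and groups that do not overlap; where fewer than 5 genes pass in a direction, the genes of smallest unadjusted p filled it up to 8, with the other criteria kept; for each list, its passing members or its members of highest mean CPM up to 2; and a fixed set of interferon, editing, 7SL and cell marker genes. Genes set mainly by common deletion, copy number or haplotype, such as HLA and immunoglobulin segments, were never named; the gamma-globin genes and KLRC2 were treated in the same way. Genes named outside the rule are said to have been chosen after their values were seen.

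To describe repeat content, a consensus of the AluY element was matched to the GENCODE 29 transcripts with BLAST 2.17.0 (E-value limit 1e-20). A gene with at least 1 match of any length is called Alu-bearing: 11633 of 58676 genes (19.8%), and 63.4% of the genes tested. Identity was taken only from matches of at least 200 bases, which 1300 of the 8980 Alu-bearing genes tested did not have. This step was chosen after the data were examined.

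Depth was 13747309 to 16733278 expected counts per library. No pair of libraries agreed within sampling noise. A gene at 0 counts in a group was given a floor of 3 counts over the group; floors and counts cover counting error only. The procedure was tested on simulated data: counts for 13743 genes of this comparison gave calls for 20.3% of 64 genes changed 2-fold, 77.8% of 63 changed 4-fold and 96.7% of 60 changed 8-fold, all with the right sign, and 12 calls among 13556 unchanged genes. In a separate simulation a list lowered 1.5-fold was called (camera adjusted p = 3.47e-07), and no other list was. Simulated genes were drawn independently, so this does not test camera on lists whose members move together. The erythroid list, for 1, had an estimated correlation of 0.82. Alternatives covered the normalization, the low-count filter, the tool (DESeq2 1.42.0, limma-voom, the robust edgeR fit), TPM in place of counts, removal of hemoglobin and other abundant RNAs, erythroid and neutrophil levels as covariates, a replicate block and each library left out in turn. FPKM values were not used.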

Results

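RNA sequencing of whole blood compared 3 MS-C patients, sampled after a first clinical event that preceded a diagnosis of relapsing remitting multiple sclerosis, with 3 healthy controls (HC). The series title names double-stranded RNA of Alu elements, the most numerous short repeats of the human genome, and type I interferon responses, so that the comparison addresses whether blood RNA at this stage differs from that of controls in these respects. Expected counts summed to 16397296, 16733278 and 14244081 in MS-C 1 to 3 and to 16516177, 15836679 and 13747309 in HC 1 to 3. The edgeR and exact permutation p-values below measure spread between these samples. Camera's preset correlation takes the members of a list as nearly independent, and 0 lists passed with the correlation estimated. Fisher's exact test and the permutation tests on counts per kilobase and on the correlation over lists run over genes or lists, not samples.

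Most counts of all 6 libraries belonged to ribosomal DNA and to genes that carry an Alu. Long non-coding RNA genes annotated within the ribosomal DNA arrays of chromosome 21 took 45.2% ± 10.1 of the expected counts in MS-C and 42.9% ± 10.1 in HC (SD, n = 3 each; exact permutation p = 0.8). Among them FP236383.2 (chromosome 21, 8393419 to 8394341, GRCh38), FP671120.3 and FP236383.3 each held a mean of 14.7%, the same share for all 3 copies. Outside this locus, Alu-bearing genes took 83.5% ± 4.51 of the counts in MS-C and 83.1% ± 5.91 in HC (exact permutation p = 0.8). Genes with an Alu match of at least 95% identity took 11.3% ± 0.862 and 10.8% ± 2.02 (exact permutation p = 0.8). Neither share differed by more than the spread between samples.

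MFN1, which encodes a mitochondrial fusion protein, was the most abundant gene outside the locus, with 1.93% of all counts, and its transcripts match the Alu consensus at 98.9% identity (MFN1 was chosen after its values were seen). RN7SL2, the RNA of the signal recognition particle, held 0.736% of all counts and the beta-globin gene HBB 0.722%, an order that turned as a mean share of the counts outside the locus (1.35% and 1.46%). Hemoglobin genes together took 1.84% ± 1.48 of the counts in MS-C and 1.30% ± 0.851 in HC (exact permutation p = 0.5). MS-C 3 had the highest hemoglobin share, 3.54%, and HC 2 followed with 2.29%. These 2 libraries also had the largest shares of the ribosomal DNA locus, 55.4% and 54.5%, and the smallest shares of Alu-bearing genes outside it, 78.3% and 76.4%. HC 2 stood apart on the first principal component, which held 47.3% of the variance, and MS-C 3 on the second, which held 20.04%.

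**Figure D1:**
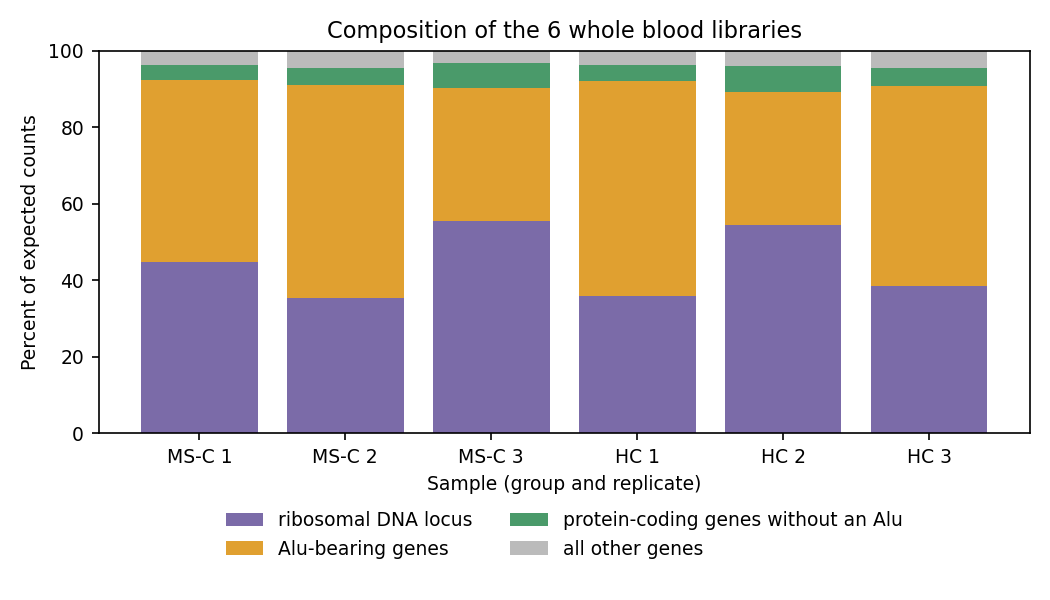
Percent of the expected counts (vertical axis) in each of the 6 libraries (horizontal axis), stacked by class of gene. The ribosomal DNA locus takes 35.2% to 55.4% of the counts and Alu-bearing genes 34.7% to 56.2%, and the MS-C and HC libraries overlap in both.

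One gene differed between the groups at the threshold. Of 14169 genes tested, edgeR's quasi-likelihood test called 1, NPIPB9 (chromosome 16, 28751787 to 28772807, GRCh38), at an adjusted p of 0.0329. No count was assigned to it in MS-C, against 133 counts over the 3 HC libraries (2.77 CPM ± 0.247, SD, n = 3), so that it was at least 39.5-fold lower in MS-C with a floor of 3 counts over the group. NPIPB9 belongs to the NPIP family of near-identical gene copies, so its counts are uncertain. The 9 family members tested summed to 180 CPM ± 14.4 in MS-C and 242 CPM ± 32.0 in HC (exact permutation p = 0.1, the smallest possible). The call ended when MS-C 1, MS-C 2, HC 2 or HC 3 was left out, each giving 0 genes, while 7 genes were called without HC 1 and 3 without MS-C 3. DESeq2 called 16 genes, and limma-voom 1.

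At unadjusted p below 0.05 there were 956 genes against 708 expected by chance, 206 higher and 750 lower in MS-C, and 12.3% of the genes tested had groups that did not overlap, where chance gives 10%. With library totals in place of TMM, which moved the median log2 fold change of all genes to -0.25, 95.7% of such genes were lower in place of 78.5%. Without HC 2 the split was 324 higher and 352 lower. The split also differed with repeat content: genes with an Alu match had a median log2 fold change of 0.11 and those without one of -0.37, and the low-p genes were 260 lower and 128 higher with a match, and 490 lower and 78 higher without one. When the genes without a match were scaled and tested alone, their low-p genes were 139 lower and 213 higher. The gap between the medians of these classes was 0.0851 without HC 2 and 0.756 without HC 1.

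Markers of natural killer and cytotoxic cells fell as a list by camera (adjusted p = 0.000123), but not with an estimated correlation (adjusted p = 0.556) or by fry (adjusted p = 0.361). Of the 11 members tested, 10 had negative fold changes (median log2 fold change -0.62). All 3 MS-C libraries lay below the 3 HC libraries in mean level, 2.02 ± 0.0752 against 2.77 ± 0.354 log2 CPM (SD, n = 3). The exact permutation p was 0.1, the smallest possible, and 0.58 adjusted over the 29 lists. GNLY, which encodes the cytotoxic granule protein granulysin, was at 7.04 CPM ± 1.12 in MS-C and 25.7 CPM ± 14.2 in HC. NKG7, a granule membrane protein gene chosen after its values were seen, was at 1.37 and 3.44 CPM, whereas PRSS23, the only member with a positive value, had a log2 fold change of 0.21. KLRD1, a receptor gene of these cells, had -0.50. No member passed over all genes tested, and 2 were lower when adjusted over the list alone. FCGR3A (chromosome 1, 161541759 to 161550737, GRCh38), the IgG receptor of natural killer cells and a subset of monocytes, was at 5.74 CPM ± 0.451 in MS-C and 13.6 CPM ± 0.881 in HC, 2.37-fold lower with a log2 fold change of -1.24 ± 0.24 (SE), but did not pass (edgeR adjusted p = 0.358). A near-identical gene copy can share reads with it.

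Other lymphocyte lists lay on the same side. T cell markers fell (20 of 23 members negative, median -0.39, camera adjusted p = 0.00255), with an adjusted p of 0.695 with an estimated correlation. CD3E, a chain of the T cell receptor complex, was at 6.35 CPM ± 1.64 in MS-C and 10.3 CPM ± 4.41 in HC, and CD3G and CD96 had log2 fold changes of -0.10 and 0.18. Without MS-C 3 the call on this list was lost (adjusted p = 0.130), and without HC 2 the median was -0.22. Plasma cell markers fell (7 of 7 negative, median -0.57, adjusted p = 0.0181, and 0.695 with an estimated correlation), among them XBP1, a transcription factor of secretory cells, at -1.08 and CD38 at -0.57. That call was lost without HC 2 (adjusted p = 0.201), HC 3 (0.0644) or MS-C 3 (0.1005). B cell markers did not pass (12 of 17 negative, median -0.54, and -0.98 to 0.09 with 1 library left out, adjusted p = 0.331); MS4A1, which encodes CD20, reached 10.3 CPM in HC 2 and at most 2.55 CPM in the other libraries. FAM129C and SPIB, which carry Alu matches, had 0.23 and 0.20. Of the B cell markers, 5 of 7 with an Alu match and 0 of 10 without one had positive fold changes. Genes near multiple sclerosis risk variants outside the HLA region fell (29 of 35 negative, median -0.30, adjusted p = 0.00457, and 0.695 with an estimated correlation), although IKZF3, a lymphoid transcription factor, and TNFSF14 had 0.09 and 0.22. Without HC 2, the library with the highest level of this list, the median was -0.07 and the call was lost (adjusted p = 0.217); without HC 1 or HC 3 the median was -0.47 or -0.54. Helper and regulatory T cell subset genes did not pass (adjusted p = 0.995), and 1 member, the chemokine receptor gene CCR4, was higher when adjusted over the list alone, at 74.8 CPM ± 14.6 against 45.4 CPM ± 6.60 in HC. CCR6 had 0.10.

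A rise of type I interferon-stimulated genes in MS-C was not shown. Of the 46 members tested 40 had negative fold changes (median -0.30), and the list fell by camera (adjusted p = 0.00541) but had an adjusted p of 0.801 with an estimated correlation. The level differed more between people of a group than between the groups. MX1, an antiviral GTPase gene, was at 99.4, 11.8 and 21.9 CPM in MS-C 1 to 3 and at 116, 19.98 and 23.2 CPM in HC 1 to 3, and IFI44L at 14.1, 1.10 and 2.88 against 21.8, 4.39 and 5.25 CPM. Mean list levels were 2.96 ± 0.641 in MS-C and 3.36 ± 0.497 log2 CPM in HC (SD, n = 3; exact permutation p = 0.5). Without HC 1 the median was 0.06, and without MS-C 1 it was -0.85, without HC 3 -0.45, without MS-C 3 -0.16 and without MS-C 2 -0.14. The call was lost without HC 1, MS-C 2 or MS-C 3 (adjusted p = 0.898, 0.330 and 0.228). IFIT1, ISG15 and OAS1 had log2 fold changes of -0.40 ± 0.67, -0.69 ± 0.68 and -0.21 ± 0.27 (SE), and TRIM22 had -0.02. Without HC 1, IFIT1 and ISG15 had 0.48 and 0.43, and without MS-C 1 they had -1.86 and -1.50.

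Interferon-gamma-associated genes fell (17 of 21 negative, median -0.30, camera adjusted p = 0.00674, and 0.695 with an estimated correlation). The 2 groups did not overlap in mean level (exact permutation p = 0.1, the smallest possible, and 0.58 adjusted over the 29 lists). The guanylate-binding protein genes GBP5 and GBP1, chosen after their values were seen, both had -0.74. IRF1 and APOL6, the most abundant members, had -0.09 and 0.13, and both carry Alu matches. Members of this list with an Alu match had a median of -0.09 and those without one -0.68. The call on this list was lost without HC 1 (adjusted p = 0.245) or MS-C 2 (0.0505). Interferon receptors and JAK-STAT components did not pass (median -0.15, and -0.34 to -0.01 with 1 library left out, camera adjusted p = 0.534). IFNAR1 and IFNAR2, the receptor chains for type I interferon, had 0.49 ± 0.24 and 0.13 ± 0.19 (SE), and IFNLR1 had 0.23.

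Sensors of double-stranded RNA and other nucleic acids fell as a list (24 of 31 negative, median -0.21, camera adjusted p = 0.0409), with an adjusted p of 0.695 with an estimated correlation. Its members IFIH1 and DDX58, cytosolic RNA sensors, had log2 fold changes of -0.30 ± 0.34 and -0.16 ± 0.34, their adaptor MAVS 0.16 ± 0.22, and the kinase EIF2AK2 0.00 ± 0.39 (SE). Without HC 1, EIF2AK2 had 0.65. MAVS carries 9 Alu matches and EIF2AK2 5, whereas IFIH1 and DDX58 carry none. The call was lost without HC 1, MS-C 2 or MS-C 3 (adjusted p = 0.613, 0.177 and 0.213), and without MS-C 1 the median was -0.32. Editing enzymes and Alu or double-stranded RNA binding proteins did not pass (median -0.23, and -0.40 to -0.06 with 1 library left out, adjusted p = 0.143). ADAR, the main adenosine-to-inosine editing enzyme of blood, was at 166 CPM ± 8.82 in MS-C and 174 CPM ± 29.7 in HC (log2 fold change -0.07 ± 0.20, SE). ADARB1 had -0.31 ± 0.47 (SE), and 0.34 without HC 2. PNPT1 and ELAVL1 had 0.26 and 0.27.

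Erythroid, platelet and small structured RNAs were on the higher side. All 30 erythroid and reticulocyte genes tested had positive fold changes (median 0.90, camera adjusted p = 9.95e-05, and 0.697 with an estimated correlation), HBB being at 5206, 3213 and 25946 CPM in MS-C 1 to 3 and 3210, 8768 and 2681 CPM in HC 1 to 3. HBA2 had 1.00 ± 0.61 (SE). Without MS-C 3, the library richest in hemoglobin, the median was -0.34 and the call was lost (adjusted p = 0.556); without HC 1, HC 2 or HC 3 the median was 0.58, 1.94 or 0.57. Platelet markers rose (13 of 15 positive, median 0.83, adjusted p = 0.000152, and 0.695 with an estimated correlation), with 2 members higher when adjusted over the list alone. GP1BB, a chain of the von Willebrand factor receptor, was at 3.17 CPM ± 1.48 in MS-C and 1.00 CPM ± 0.334 in HC. PPBP had a log2 fold change of 1.39 (0.44 without MS-C 3 and 2.32 without HC 2) and NRGN 0.91 (1.56 without HC 2). Without HC 2 the median of this list was 1.64, without MS-C 1 it was 1.25, and without MS-C 3, HC 1 or HC 3 it was 0.46, 0.55 or 0.57.

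The snoRNA and scaRNA list, guide RNAs for the modification of ribosomal and spliceosomal RNA, rose (10 of 12 positive, median 0.59, adjusted p = 0.000123, and 0.695 with an estimated correlation), and 4 members were higher when adjusted over the list alone. SCARNA10 was at 52.7 CPM ± 16.1 in MS-C and 19.8 CPM ± 8.92 in HC, SNORD17 had a log2 fold change of 1.99 ± 0.46 (SE), and SCARNA2 had 0.60. Without MS-C 1 the median was 0.21, without HC 3 it was 0.39, without MS-C 2 it was 0.94 and without HC 2 it was 1.53. The list of 7SL, 7SK, Y, vault and other structured RNAs rose (7 of 9 positive, median 0.40, adjusted p = 0.00541, and 0.695 with an estimated correlation), a call lost without HC 1 (adjusted p = 0.189) or MS-C 3 (0.0676); without HC 2 the median was 0.77. RN7SL1 was at 4283 CPM ± 548 in MS-C and 2586 CPM ± 527 in HC (log2 fold change 0.73 ± 0.35, SE, edgeR adjusted p = 0.713), and its near-identical copy RN7SL2 at 7216 CPM ± 1224 and 7517 CPM ± 1869. Summed, these copies gave 11499 CPM ± 1592 and 10102 CPM ± 2254 (exact permutation p = 0.5).

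Mitochondrially encoded genes rose as a list (13 of 15 positive, median 0.54, camera adjusted p = 0.000152, and 0.556 with an estimated correlation). The groups did not overlap in mean level (exact permutation p = 0.1, the smallest possible, and 0.58 adjusted over the 29 lists). All 13 protein-coding members had positive fold changes, from 0.20 to 1.01, and both ribosomal RNAs, MT-RNR1 and MT-RNR2, had negative ones, -0.40 and -0.31. Without MS-C 2 the median was 0.22. The share of all counts from the mitochondrial genome lay the other way, 0.271% ± 0.0586 in MS-C and 0.363% ± 0.146 in HC (SD, n = 3; exact permutation p = 0.4). Most of that share came from both ribosomal RNAs, so it says little about the protein-coding members. Over the libraries of a group, MT-RNR2 had 69561 counts in MS-C and 104957 in HC, and MT-RNR1 18719 and 28876. Nuclear oxidative phosphorylation genes did not pass (median 0.07, adjusted p = 0.308), NDUFS1 and NDUFV3 having 0.18 and 0.17.

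**Figure D2:**
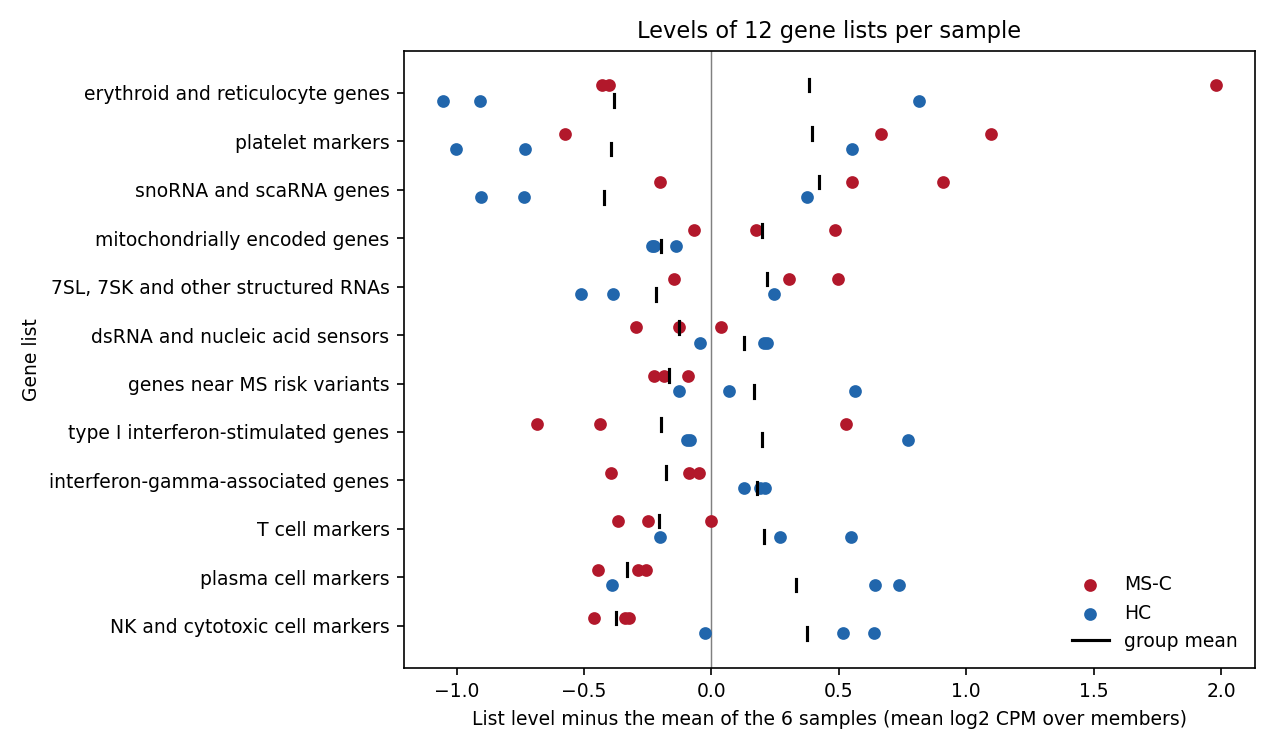
Mean log2 CPM of the 12 called gene lists in each sample, as the difference from the mean of the 6 samples (horizontal axis), with 1 point per library and a black bar at the group mean. The MS-C and HC points do not overlap for natural killer, interferon-gamma and mitochondrially encoded genes, and overlap for the other 9 lists. For each of these 3 lists the exact permutation p was 0.1, the smallest possible, and 0.58 adjusted over the 29 lists.

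By fry, a test without the preset correlation, none of the 29 lists passed (lowest adjusted p = 0.361). The remaining 17 lists did not pass camera. Myeloid lists gave medians of 0.09 for neutrophil markers (adjusted p = 0.659), -0.34 for immature neutrophil granule genes (0.678), -0.27 for monocyte markers (0.0528), 0.23 for eosinophil and basophil markers (0.331) and 0.15 for dendritic cell markers (0.484). Monocyte markers were called lower under 7 of 23 alternatives (lowest adjusted p = 0.00109), with a median of -0.60 to -0.13 when 1 library was left out. Such medians were -0.13 to 0.16 for neutrophil markers and -0.83 to -0.06 for immature neutrophil granule genes. They were -0.10 to 0.62 for eosinophil and basophil markers and -0.02 to 0.16 for dendritic cell markers. CSF3R and KCNJ15 had -0.10 and 0.17, CTSS and LYZ 0.13 and -0.01, AZU1 and CEACAM8 -0.04 and 0.18, MS4A2 and SIGLEC8 0.26 and 0.46, and TCF4 and SERPINF1 0.15 and 0.18. CD14, the monocyte coreceptor gene, was at 4.72 CPM ± 1.85 in MS-C and 6.35 CPM ± 1.77 in HC. NF-kB targets and inflammatory cytokines had a median of -0.17 (adjusted p = 0.445), with SOD2 and REL at 0.19 and -0.02. Immediate early and heat shock genes had 0.00 (0.995), glucocorticoid-responsive genes -0.41 (0.0648) and proliferation genes 0.09 (0.542). With 1 library left out the medians were -0.33 to 0.05 for NF-kB targets and -0.23 to 0.07 for immediate early and heat shock genes. Glucocorticoid-responsive genes then had -0.51 to -0.16 and proliferation genes -0.23 to 0.23. HSPA1A, a heat shock protein gene, and NR4A1 had 0.85 and 0.24, IRS2 and TXNIP 0.18 and -0.84, and BIRC5 and RRM2 0.38 and 0.58. Cytosolic ribosomal protein genes (adjusted p = 0.539) had a median of -0.06 while camera's direction was up, replication-dependent histone genes (0.934) a median of -0.07 with a mean of 0.01 and camera's direction up, and zinc finger genes (0.534) a median of 0.03 with a mean of -0.06 and camera's direction up. RPL7L1 and RPS27L had 0.23 and 0.27, HIST1H2BN and HIST2H2BC 0.35 and -0.14, and ZNF426 and ZNF101 0.19 and 0.24.

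Other genes with the smallest p and groups that did not overlap did not pass either (edgeR adjusted p of 0.358 to 0.713). Lower values in MS-C were those of PGGHG, a glucosidase gene, at 7.88 CPM ± 0.618 against 19.6 CPM ± 4.57, UPK3BL1 at 50.04 CPM ± 2.34 against 97.7 CPM ± 7.73, the olfactory receptor gene OR52K2 with a log2 fold change of -2.24 ± 0.44, the cell adhesion gene NECTIN2 with -3.01 ± 0.71 and the NPIP family member NPIPB12 with -1.71 ± 0.34 (SE). Higher values in MS-C were those of RAB2B, a vesicle transport gene, with 1.54 ± 0.42, the U2 spliceosomal RNA gene RNU2-2P with 1.87 ± 0.46, MTRNR2L11 with 1.29 ± 0.34, HSPA1L with 1.05 ± 0.29 and MYADM with 0.85 ± 0.24 (SE). Single libraries carried part of these values: NECTIN2 had -2.05 without HC 2, RAB2B 0.84 without MS-C 3 and RNU2-2P 1.01 without MS-C 1. UPK3BL1, NPIPB12, RNU2-2P, MTRNR2L11, HSPA1A and HSPA1L have near copies elsewhere in the genome, so their counts are uncertain.

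**Figure D3:**
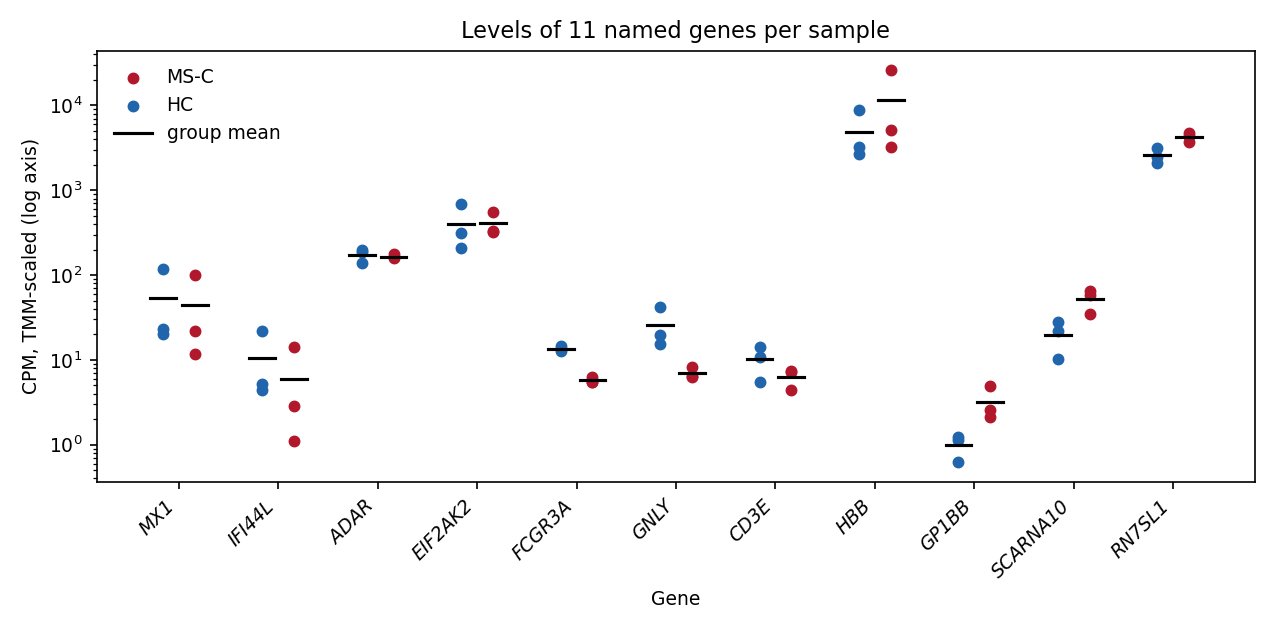
TMM-scaled CPM of 11 named genes (log axis), with 1 point per library and a black bar at the group mean (n = 3 each). The MS-C points lie below the HC points for FCGR3A and GNLY and above them for GP1BB, SCARNA10 and RN7SL1, and none of these genes passed edgeR's test at an adjusted p below 0.05.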

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

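The alternatives that keep only genes without an Alu match, centre the Alu-bearing and other genes separately, add the Alu-bearing share as a covariate or leave out MS-C 3 and HC 2 together (the libraries richest in the ribosomal DNA locus) were chosen after seeing the data; all others were fixed before the data were examined. The number of genes changed between MS-C and HC, 1 by edgeR, was 1 with DESeq2's size factors, the robust fit, limma-voom, and hemoglobin or other abundant RNAs removed. It was 0 with upper-quartile factors, a mean count of at least 50, the neutrophil level as a covariate, log2(TPM + 1) without a filter, or only genes without an Alu match (352 genes at unadjusted p below 0.05 there, 213 higher and 139 lower). It was 59 with library totals only, 86 with no low-count filter, 16 with DESeq2, 4 with the erythroid level as a covariate, 4 with log2(TPM + 1), 3 with log2(TPM + 0.1), 15 with the Alu-bearing share as a covariate and 5 without MS-C 3 and HC 2; leaving out 1 library at a time gave 0 to 7. The cause was not tested. Replicate numbers gave no sign of pairing (correlations of the deviations of same-numbered samples 0.04, -0.38 and -0.18), which 3 samples a group cannot exclude. A fit with the replicate number as a block called 5 genes and 12 lists.

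Of the 29 lists, 12 were called by camera, 0 with the correlation estimated per list and 0 by fry, 5 with the erythroid level as a covariate, 5 among genes without an Alu match (all higher), and 7 to 13 with 1 library left out. The count of lists with groups that do not overlap was 3, and 7 on log2(TPM + 1) and 10 with library totals only. At 3 against 3, chance separates 10% of such comparisons, and the lowest exact permutation p adjusted over the 29 lists was 0.58. Medians that changed sign with a call on either side were those of type I interferon-stimulated genes (-0.849 to 0.0601 with 1 library left out), erythroid genes (-0.34 to 1.94), cytosolic ribosomal protein genes (-0.21 to 0.25) and B cell markers (0.40, higher, without MS-C 3 and HC 2); the cause was not tested. Of 2070 other fold changes of named genes, 1846 kept their direction and side of the threshold, 175 changed sign without a call, 41 gained and 8 lost a call. At 13747309 to 16733278 counts per library, 20.3% of the genes changed 2-fold in the simulation were called. That rate, with 200 genes changed, may be too high for these data.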

Other observations

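Only the tests on genes of other tissues were fixed before their results were seen; the tests on the gap between gene classes, its quartiles and single libraries, the correlation over lists (whose direction was first stated the wrong way round), the centring, the members of the higher lists, the natural killer list, the share of Alu-bearing genes, interferon-stimulated genes and every count of splits were chosen after the results were seen. The centring tests took the place of others, on scaling and on members without an Alu, whose results had been seen.

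Genes of other tissues were among the abundant genes: PDE6A and CRX, both genes of photoreceptors and chosen after their values were seen, ranked 23 and 33 of all genes at means of 1728 and 1475 CPM of all counts. A candidate explanation is that reads of Alu repeats were counted to genes that carry an Alu. Of 89 textbook genes of other tissues, 10 of the 20 with an Alu match reached 1 CPM and 1 of the 69 without one did (Fisher's exact p = 3.54e-07). Longer transcripts as the whole cause are argued against, since median counts per kilobase of the longest transcript were 25.2 times higher with a match. A permutation test on the difference in mean log2 counts per kilobase gave p = 1e-05, the smallest possible. The design gives no biological explanation to test here. Levels of Alu-bearing genes may hold such reads too, whichever the sign of their fold change. Among them are ADAR, MX1, OAS1, IFNAR1, IFNAR2, IFNLR1, KLRD1 and GNLY. The same holds for MAVS, EIF2AK2, PNPT1, IKZF3, TNFSF14, IRF1, APOL6, FAM129C, SPIB, CD3G, CD96 and PRSS23.

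Genes without an Alu had lower fold changes than Alu-bearing genes in MS-C, by 0.48 in median log2 fold change. The gap was above 0.2 in 3 of 4 quartiles of mean CPM (0.33, 0.40 and 0.39) but 0.03 in the most abundant one, so low counts of the genes without an Alu stay open as a cause. The gap was 0.0851 without HC replicate 2 and 0.358 to 0.756 without any 1 of the others (highest without HC 1), so 1 library with another mix of RNA is a candidate cause, and a difference between the groups stays open. After each class was centred on its own median, 6 of the 7 lower lists were still called. The exception was interferon-gamma-associated genes (median -0.30 before and -0.21 after, camera adjusted p = 0.0507). The calls kept argue against the gap as the whole cause of those 6 camera calls, all made with the preset correlation. Centring took 1 median per class, however, while the gap differed with abundance. No lower list was called among genes without an Alu alone. In 5 of the 5 higher lists the members without an Alu had a median above 0 (0.40 to 0.90). A gap that lowers such genes would not raise them. All 5 lists were picked for being higher, however. The mitochondrial and structured RNA lists hold only such members, so for them this outcome was fixed in advance. It was nearly fixed for the snoRNA and platelet lists, in which 11 of 12 and 12 of 15 members lack an Alu. In the erythroid list 19 of 30 members lack one, so the count of 5 lists carries little weight. Across the 29 lists the percent of Alu-bearing members and the median log2 fold change gave a Spearman rho of -0.18 (permutation p = 0.343; Pearson r = -0.40, permutation p = 0.0298), across lists that share genes; a gap that moved the lists would give a positive rho, so the negative values run against it, but the rho lay within its permutation spread.

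Low natural killer and cytotoxic markers were the list called under the most alternatives among the lower lists (20 of 23; adjusted p from 2.46e-05 to 0.556). The list was still called after centring (camera adjusted p = 5.62e-05 with the preset correlation). Within the limits of centring given above, that argues against the gap between gene classes as the whole cause of the call. No lower list was called among genes without an Alu alone, however, so the gap is not excluded as a part of the cause. A smaller share of these cells in blood could account for 10 of 11 members being lower, but no cell counts were used here, and the fall in T cell and plasma cell lists leaves a wider shift in cell makeup open. Disease state stays open as untested.

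The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 1 gene and the highest of the other splits 0, so 1 of 10 splits gave as many. For lists the real split gave 12 and the highest other 16, with 3 of 10 splits at least as large; for genes at unadjusted p below 0.05 it gave 956 and the highest other 2631, again 3 of 10. That split, of MS-C 1, MS-C 2 and HC 1 against the others, followed the first principal component, which points to a structure of the samples apart from the groups. For the gap between Alu-bearing genes and others it gave 0.48 and the highest other 0.74, with 5 of 10 splits at least as large. The absolute median log2 fold change of natural killer and cytotoxic markers was 0.62 in the real split and 0.67 in the highest other, with 3 of 10 splits at least as large, and that of erythroid genes 0.90 and 2.03, with 5 of 10.

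Hypotheses close to the series title were tested as differences in means. The first used the share of counts in Alu-bearing genes outside the ribosomal DNA locus. That share takes all reads of such genes, not reads of Alu repeats alone, and does not measure double-stranded RNA. A larger share in MS-C was taken to mean groups that do not overlap. The mean was 0.479 percentage points higher in MS-C and the groups overlapped (exact permutation p = 0.8). For a rise of interferon-stimulated genes in MS-C, the same was asked of their list level. The difference in mean level, MS-C minus HC, was -0.40 log2 CPM and the groups overlapped (exact permutation p = 0.5). Neither test decides with 3 samples a group.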
